A study of Mus musculus with 8 samples.

How the data were processed

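Messenger RNA from splenic B220-positive cells of wild-type (WT) and BCL6BTBmut (BTB) mice, labelled C57/BL6, was sequenced at T0 and T12 as poly-A selected TruSeq libraries, 2 per group and 8 in all. The submitters' processing notes name STAR, HTSeq, edgeR and the build mm10, with versions not given. The annotation, filters and strand setting of the counting are not stated.

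The deposited table holds raw counts per Ensembl gene, in 1 column per library and 38124 genes. The authors also deposited 2 tables, 1 per genotype, whose columns per the file headers are a log2 fold change, a mean log2 CPM, a p-value and an adjusted p-value. Their direction is not in the header and was checked against the counts, where positive values are higher at T12. The file names give the genotype, a human gene identifier, a CPM limit (cpm-3) and FDR0.05, and the tables reach down to a mean log2 CPM of -2.97 and -2.99 and up to an adjusted p of 0.05. How genes were matched to human identifiers is not stated.

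Gene names, positions and types came from GENCODE mouse release 21, on the same build, and 36345 of the 38124 identifiers had a name. The 1779 without a name took 0.387% to 0.587% of the counts in a library. Total counts ran from 27023808 to 40000629 and no library was left out. Within groups the chi-square per degree of freedom of the counts was 35.8 for WT T0 and 15.3 for WT T12. It was 12.9 for BTB T0 and 37.9 for BTB T12, where counting error alone gives 1. This value pools all tested genes and is driven by those with many counts, which spread between libraries beyond counting error. For genes with few counts, depth can limit the precision too. Counts per gene cannot show whether a library carries the Bcl6 mutation.

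Tests used edgeR 4.0.16 and limma 3.58.1 in R 4.3.3, with DESeq2 1.42.0 as an alternative, and figures used matplotlib 3.10.9 in Python 3.11.15. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 15692. Counts were scaled by TMM, and log2 CPM used a prior count of 2. All 8 libraries entered 1 quasi-likelihood fit of 4 group means with 4 residual degrees of freedom, and 5 contrasts were tested: T12 against T0 in each genotype, the difference of these responses, and BTB against WT at each time. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of its contrast. The SE of a log2 fold change is its size divided by the square root of the quasi-likelihood F.

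Before the data were examined, 27 gene lists, 13 genes of interest, the groups, tests, alternatives and the rule for named genes were fixed. The rule named the 13 genes in every contrast, then up to 6 genes per direction with the largest change among called genes with a mean log2 CPM of at least 4 and no overlap between replicates, leaving out predicted and immunoglobulin genes, and up to 3 members per list with the smallest p. Where fewer than 6 passed in a direction in the interaction or between genotypes, the rule dropped the limit on log2 CPM, as it did for the interaction. Lists were tested with camera at an inter-gene correlation of 0.01, again with an estimated correlation, and with fry, which tests whether a list's genes move on balance in 1 direction and does not compare them with other genes. P-values of lists were adjusted over the 27 lists of a contrast. With an estimated correlation, camera tests on the 4 residual degrees of freedom, so calls can be lost without strong correlation. In WT the B cell identity list had an estimated correlation of 0.00901, below the preset 0.01. Its unadjusted camera p still went from 1.06e-13 to 0.00167. A call lost in this check therefore does not show that correlation between genes produced it. "Adjusted over the list alone" means that only the members of that list were adjusted for.

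Libraries numbered alike within a genotype had deviations from their group means that correlated across genes at 0.400 in WT and 0.319 in BTB, so a fit with the number within genotype as a block is given beside the T12 against T0 contrasts and the interaction. Each group of 2 gives only 1 independent deviation. Between genotypes these correlations were 0.0350 to 0.212 over all genes and 0.394 to 0.545 over genes with a mean log2 CPM of at least 4, against 0.618 and 0.546 within WT and BTB over those genes. The titles number within genotype, so no label pairs WT with BTB, and a fit with the number across all groups as a block is given as an alternative there. The block fits left 2 residual degrees of freedom within genotype and 3 across genotypes.

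The fit was tested on simulated data with 200 changed genes of 15692 and 2 libraries per group. It recovered 81.5% in WT, 79.5% in BTB, 63.0% for the interaction, and 80.0% at each time between genotypes, with none in the wrong direction. False calls were 17 of 180 calls in WT, 14 of 173 in BTB and 7 of 133 for the interaction. Between genotypes they were 16 of 176 at T0 and 7 of 167 at T12. The false share was above the limit set for the adjusted p in every contrast except BTB against WT at T12. Calls in the data may thus include more false ones than that limit states. For the interaction the fit recovered 34.3% of genes changed 2-fold and 81.8% of those changed 8-fold.

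Alternatives were DESeq2 size factors, upper quartile scaling, library totals alone, no low-count filter, at least 1 CPM in 3 libraries, the DESeq2 Wald test, limma-voom, a log2 fold change of at least 1, the block, fits of only the 4 libraries compared, and leaving out each library in turn. When 1 library was left out, the lone library of its group was assumed to vary like the others. A covariate for genes of red cells and platelets, and leaving out X and Y genes, were added after the data were seen.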

Results

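Messenger RNA was sequenced from splenic B cells, taken as B220-positive cells, of wild-type mice (WT) and of mice with a mutation in the BTB domain of the transcriptional repressor Bcl6 (BCL6BTBmut in the labels, BTB here). Cells were collected either unheated (T0) or 12 h after a heat shock (T12). The treatment label gives 1 h of heat at 39 °C with recovery at 37 °C, while the series description speaks of a heat shock lasting 12 h. The 8 libraries form 4 groups of 2. Total counts were 38763577 and 37610727 in WT at T0 and 28280959 and 31210509 in WT at T12. In BTB they were 40000629 and 35499847 at T0 and 29946619 and 27023808 at T12. Between 19571 and 20535 genes had at least 1 count in a library. Levels are given as CPM, counts relative to the library total after TMM scaling, as mean ± SD with n = 2 per group, and differences as log2 fold changes ± SE. Genome positions refer to mm10.

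The first principal component of log2 CPM held 76.0% of the variance and parted the T0 from the T12 libraries. On the second, which held 10.2%, the 4 WT libraries lay between 25.9 and 27.8 and the 4 BTB libraries between -31.3 and -18.0. The third held 4.92%, and on it all 4 libraries numbered 1 lay above 0 and all 4 numbered 2 lay below 0. Genes of red cells and platelets took 0.123% to 0.232% of the counts in the libraries numbered 1 and 0.390% to 0.767% in those numbered 2. Immunoglobulin genes took 1.90% to 2.66% of the counts at T0 and 1.09% to 1.97% at T12. P-values measure the spread between libraries only, because the labels do not say whether replicates came from separate animals.

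**Figure D1:**
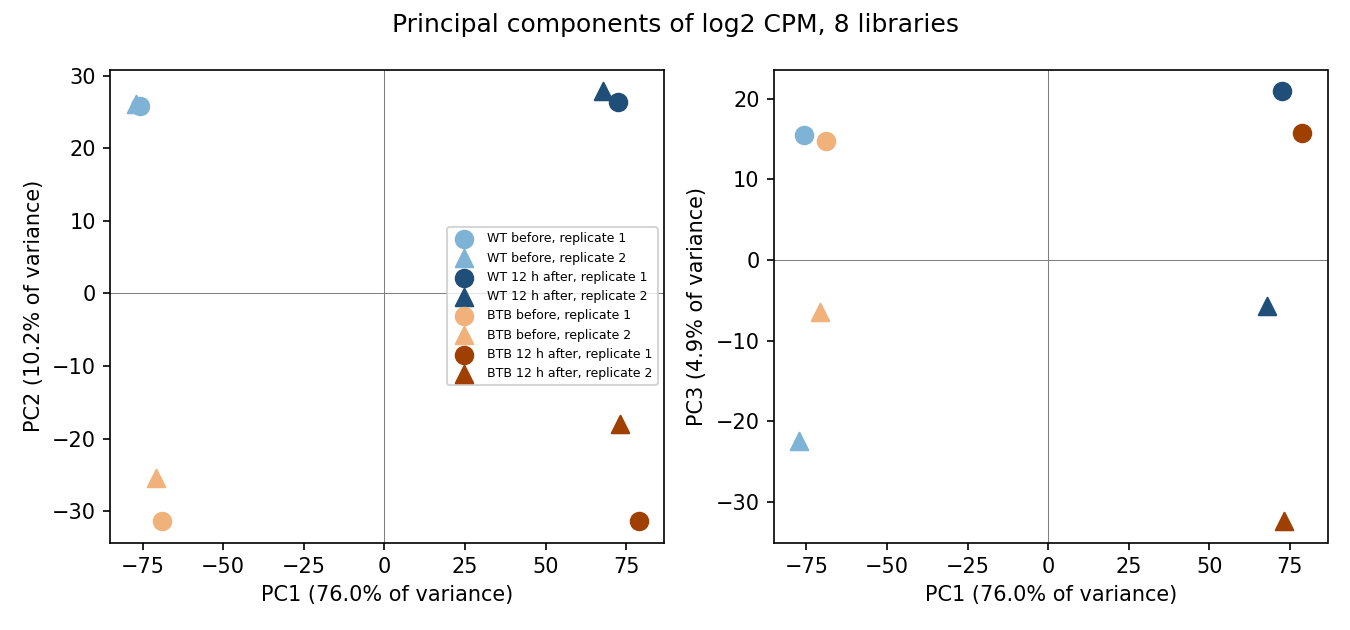
Principal components of log2 CPM for the 8 libraries, with component 1 against component 2 on the left and against component 3 on the right; color gives genotype and time, and marker shape the replicate number. Component 1 (76.0% of the variance) parts the times, component 2 (10.2%) the genotypes and component 3 (4.92%) the replicate numbers.

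In WT B cells, 23 of 24 genes of the amino acid and integrated stress response, 12 of 21 targets of p53 and the inducible Hsp70 genes were higher at T12, while most immediate early, B cell identity, cell cycle and interferon-stimulated genes were lower. Of these lists, only that of B cell identity was still called with an estimated correlation between genes. Here and below, that check rests on 4 residual degrees of freedom and is hard to pass, so a lost call does not explain a list away. Trib3 (ENSMUSG00000032715, chromosome 2, 152337422 to 152344032), a pseudokinase induced by ATF4 and CHOP, rose from 1.13 ± 0.0705 to 357 ± 22.9 CPM, a log2 fold change of 8.30 ± 0.11. Vegfa, a growth factor of blood vessels, rose by 6.89 ± 0.10, the cyclic AMP-responsive regulator Crem by 5.20 ± 0.11, and Bbc3, which encodes the pro-apoptotic protein PUMA, by 4.92 ± 0.17. Among genes with a mean log2 CPM of at least 4 that met the rule for largest changes, the largest decreases were in the immediate early genes Fosb (ENSMUSG00000003545, -7.82 ± 0.18), Fos (-5.45 ± 0.20) and Klf4 (-4.89 ± 0.21), in the marginal zone receptor S1pr3 (-4.46 ± 0.12), in Fgd2 (-4.07 ± 0.12) and in the small GTPase Rhob (-3.91 ± 0.22). Fosb fell from 871 ± 136 to 3.86 ± 0.0233 CPM. Of 15692 genes tested, 9901 changed at an adjusted p under 0.05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 4809 upward and 5092 downward. By at least 1 on the log2 scale, 1707 rose and 2525 fell. The adjusted p was 1.07e-07 for Trib3, 1.37e-07 for Vegfa and 3.96e-07 for Fosb. With the replicate number within the genotype as a block, 10287 genes changed.

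Among heat shock genes, Hspa1a (ENSMUSG00000091971, chromosome 17, 34969190 to 34972156) rose in WT from 1.54 ± 0.677 to 51.7 ± 3.21 CPM (5.08 ± 1.29, adjusted p = 0.0107). Its near-identical neighbor Hspa1b (ENSMUSG00000090877) rose from 3.22 ± 2.06 to 95.3 ± 17.3 CPM (4.90 ± 1.43, adjusted p = 0.0192). How reads shared by these copies were counted is not stated, so the level of each is uncertain. The call of Hspa1a was lost with limma-voom (adjusted p = 0.0781) and without WT T0 replicate 1 (0.0680). That of Hspa1b was lost with limma-voom (0.129) and without WT T0 replicate 1 (0.103), WT T0 replicate 2 (0.0650) or WT T12 replicate 2 (0.0521). Hsph1, which encodes a cochaperone of the Hsp110 family, rose by 1.53 ± 0.24 and the heat shock regulator Hsf1 by 0.63 ± 0.09, and the constitutive chaperone Hspa8 changed by -1.36 ± 0.18. Hsp90aa1 (0.38 ± 0.28) and Dnajb1 (0.20 ± 0.35) were not called. Of 26 measured members of the heat shock list, 9 rose and 6 fell, the same counts as when adjusted over the list alone, and camera did not call the list (adjusted p = 0.483).

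Bcl6 itself (ENSMUSG00000022508, chromosome 16, 23965052 to 23988852) fell in WT from 157 ± 50.2 to 73.6 ± 12.8 CPM (-1.09 ± 0.21, adjusted p = 0.00281). Of the genes named in advance as Bcl6 or stress targets, the cell cycle inhibitor Cdkn1a rose by 4.45 ± 0.16, the plasma cell regulator Prdm1 by 0.99 ± 0.15, the DNA damage kinase Atr by 0.73 ± 0.08 and Trp53, which encodes p53, by 0.62 ± 0.05. Tox, which encodes an HMG-box regulator, was at 1.74 ± 1.32 and 1.99 ± 0.854 CPM and was not called. The list of Bcl6 targets had 17 members that rose and 9 that fell of 30, also when adjusted over the list alone, with camera adjusted p = 0.0645, 0.0119 with the replicate number as a block and 0.305 with an estimated correlation.

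By group, 23 of 24 measured genes of the amino acid and integrated stress response rose in WT and 0 fell, the same when adjusted over the list alone, with a median of 2.97 (camera adjusted p = 6.70e-16, and adjusted p = 0.222 with an estimated correlation). The one-carbon enzymes Mthfd2 and Shmt2 rose by 4.15 ± 0.07 and 3.40 ± 0.07. Genes of the oxidative stress list rose in 10 cases and fell in 4 of 19, with Sqstm1 at 2.49 ± 0.12 and Fth1 at 1.81 ± 0.08 (camera adjusted p = 0.0169, and adjusted p = 0.655 with an estimated correlation). The p53 targets rose in 12 and fell in 5 of 21 (camera adjusted p = 0.0214, and adjusted p = 0.236 with an estimated correlation), with Bax at 1.62 ± 0.08. B cell activation and NF-kB genes rose in 19 and fell in 8 of 30 (camera adjusted p = 0.00577, and adjusted p = 0.222 with an estimated correlation), with Il2ra at 2.94 ± 0.10 and Slamf1 at -2.94 ± 0.11. For these 3 lists the counts adjusted over the list alone were the same.

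Among groups that were lower in WT at T12, B cell identity genes fell in 27 and rose in 2 of 30, with a median of -1.39. This list's camera call (adjusted p = 1.43e-12) held with an estimated correlation (adjusted p = 0.0451), and no other of the 11 WT calls did. The low-affinity IgE receptor Fcer2a changed by -3.71 ± 0.07 and the inhibitory receptor Cd22 by -3.28 ± 0.08. Cell cycle genes fell in 28 and rose in 2 of 30 (camera adjusted p = 2.75e-08, and adjusted p = 0.571 with an estimated correlation). Immediate early genes fell in 18 and rose in 3 of 25 (camera adjusted p = 8.39e-06, and adjusted p = 0.571 with an estimated correlation). Interferon-stimulated genes fell in 22 and rose in 0 of 30 (camera adjusted p = 2.68e-07, and adjusted p = 0.394 with an estimated correlation), with Mx1 at -4.86 ± 0.26. Marginal zone genes fell in 11 and rose in 1 of 16 (camera adjusted p = 2.73e-05, and adjusted p = 0.222 with an estimated correlation), with the complement receptor Cr2 at -3.42 ± 0.14. Germinal center genes fell in 11 and rose in 1 of 14 (camera adjusted p = 0.0358, and adjusted p = 0.655 with an estimated correlation), with Gcsam at -4.57 ± 0.74. Myeloid markers fell in 12 and rose in 0 of 19 (camera adjusted p = 7.17e-04, and adjusted p = 0.394 with an estimated correlation), with Csf1r at -4.33 ± 0.31. All 7 lists had the same counts when adjusted over the list alone.

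Camera did not call the other lists in WT, and the adjusted p-values that follow are from camera. Fry called Bcl6 targets (fry adjusted p = 1.95e-04), Bcl6 corepressors (5.33e-04) and apoptosis genes (0.00295) up. It called dendritic cell (0.00315), proteasome (0.0145) and ribosome biogenesis genes (0.0270) down. Rising and falling members numbered 6 and 9 of 22 endoplasmic reticulum stress genes (adjusted p = 0.693). They numbered 10 and 6 of 21 apoptosis genes (0.472), 10 and 6 of 20 Bcl6 corepressors (0.332) and 8 and 9 of 27 DNA repair genes (0.803). They numbered 8 and 13 of 24 trafficking genes (0.555) and 8 and 5 of 17 plasma cell genes (0.472). For cholesterol synthesis they were 5 and 10 of 24 (0.723) and for glycolysis and hypoxia 8 and 15 of 29 (0.497). For ribosome biogenesis they were 3 and 8 of 25 (0.472), for the proteasome 3 and 17 of 30 (0.0657), and for mitochondrially encoded transcripts 2 and 2 of 8 (0.723). Markers of other cells rose and fell in 10 and 11 of 25 for T and NK cells (0.600), 3 and 9 of 16 for dendritic cells (0.0773), and 3 and 2 of 17 for red cells and platelets (0.693). Counts adjusted over the list alone were the same except for Bcl6 corepressors (10 and 7), DNA repair (9 and 11), ribosome biogenesis (3 and 7) and red cells and platelets (2 and 2). Median, mean and test differed in sign for DNA repair (median -0.02, mean -0.08, test up), plasma cells (0.26, -0.05, up), glycolysis and hypoxia (-0.40, 0.00, down) and red cells and platelets (-0.01, -0.30, up). No unheated group at 12 h was analysed here, so heat and time in culture are confounded in both genotypes.

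**Figure D2:**
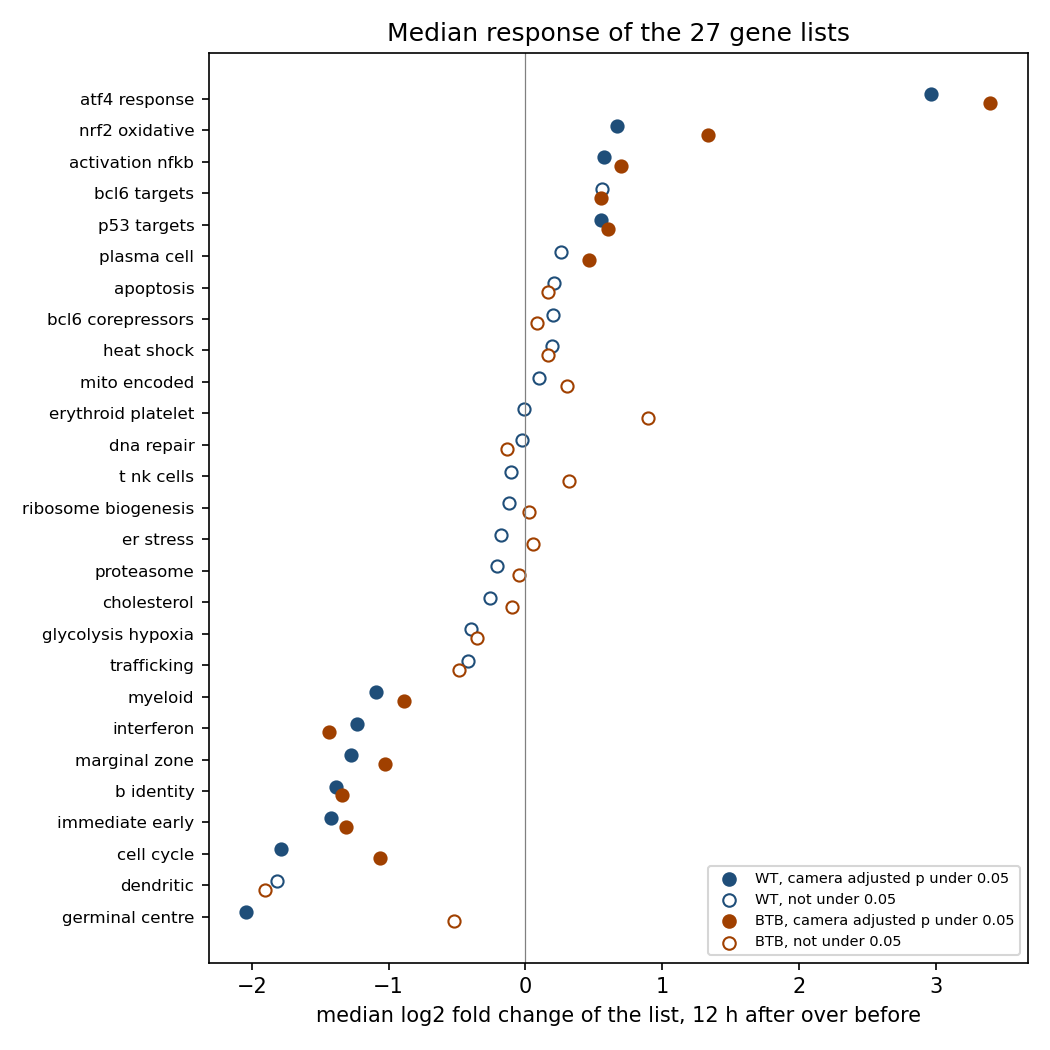
Median log2 fold change from T0 to T12 of the 27 gene lists in WT (blue) and BTB (brown), with filled points for lists that camera called at an adjusted p under 0.05 with its preset correlation. The list of the amino acid and integrated stress response has medians of 2.97 in WT and 3.40 in BTB, and that of B cell identity -1.39 and -1.34.

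In BTB B cells, 23 of 24 genes of the amino acid and integrated stress response rose between T0 and T12, and 17 of 25 immediate early and 24 of 30 B cell identity genes fell, while no list was called with an estimated correlation between genes. Trib3 rose from 0.787 ± 0.123 to 372 ± 11.7 CPM (8.87 ± 0.11, adjusted p = 8.88e-08), Vegfa by 7.27 ± 0.10, Bbc3 by 5.49 ± 0.18 and Crem by 5.09 ± 0.11. Hpgds, a prostaglandin D synthase, rose by 4.74 ± 0.23 and the oxidative stress gene Osgin1 by 4.59 ± 0.20. Fosb (-7.00 ± 0.17), Fos (-4.99 ± 0.19), Klf4 (-4.58 ± 0.21) and Egr1 (-4.08 ± 0.10) fell, as did the iron exporter Slc40a1 (-4.44 ± 0.35) and the adhesion receptor Ceacam1 (-3.81 ± 0.12). Of 15692 genes, 9616 changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4768 upward and 4848 downward. By at least 1 on the log2 scale, 1822 rose and 2300 fell. With the replicate number as a block, 10027 changed.

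Bcl6 fell in BTB from 231 ± 2.96 to 84.7 ± 6.11 CPM (-1.45 ± 0.21). Cdkn1a rose by 4.86 ± 0.16, Prdm1 by 1.69 ± 0.15, Hsph1 by 1.70 ± 0.24, Hsf1 by 0.71 ± 0.09, Atr by 0.56 ± 0.08 and Trp53 by 0.54 ± 0.05, and Hspa8 changed by -1.63 ± 0.18. Tox rose from 0.293 ± 0.0611 to 1.65 ± 0.604 CPM (2.50 ± 0.69, adjusted p = 0.0156). Its call was lost without BTB T0 replicate 1 (0.0832), BTB T0 replicate 2 (0.0545) or BTB T12 replicate 1 (0.0845). Hspa1a (1.04 ± 1.01), Hspa1b (-0.08 ± 1.15), Hsp90aa1 (-0.16 ± 0.28) and Dnajb1 (-0.36 ± 0.35) were not called. In BTB T0 replicate 1, Hspa1a stood at 68.7 CPM against 3.19 in replicate 2, and Hspa1b at 224 against 7.93. Without that library the log2 fold changes were 4.54 for Hspa1a (adjusted p = 6.38e-04) and 3.79 for Hspa1b (0.00718). Without BTB T0 replicate 2, Dnajb1 was called at -0.82 (0.0289).

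**Figure D3:**
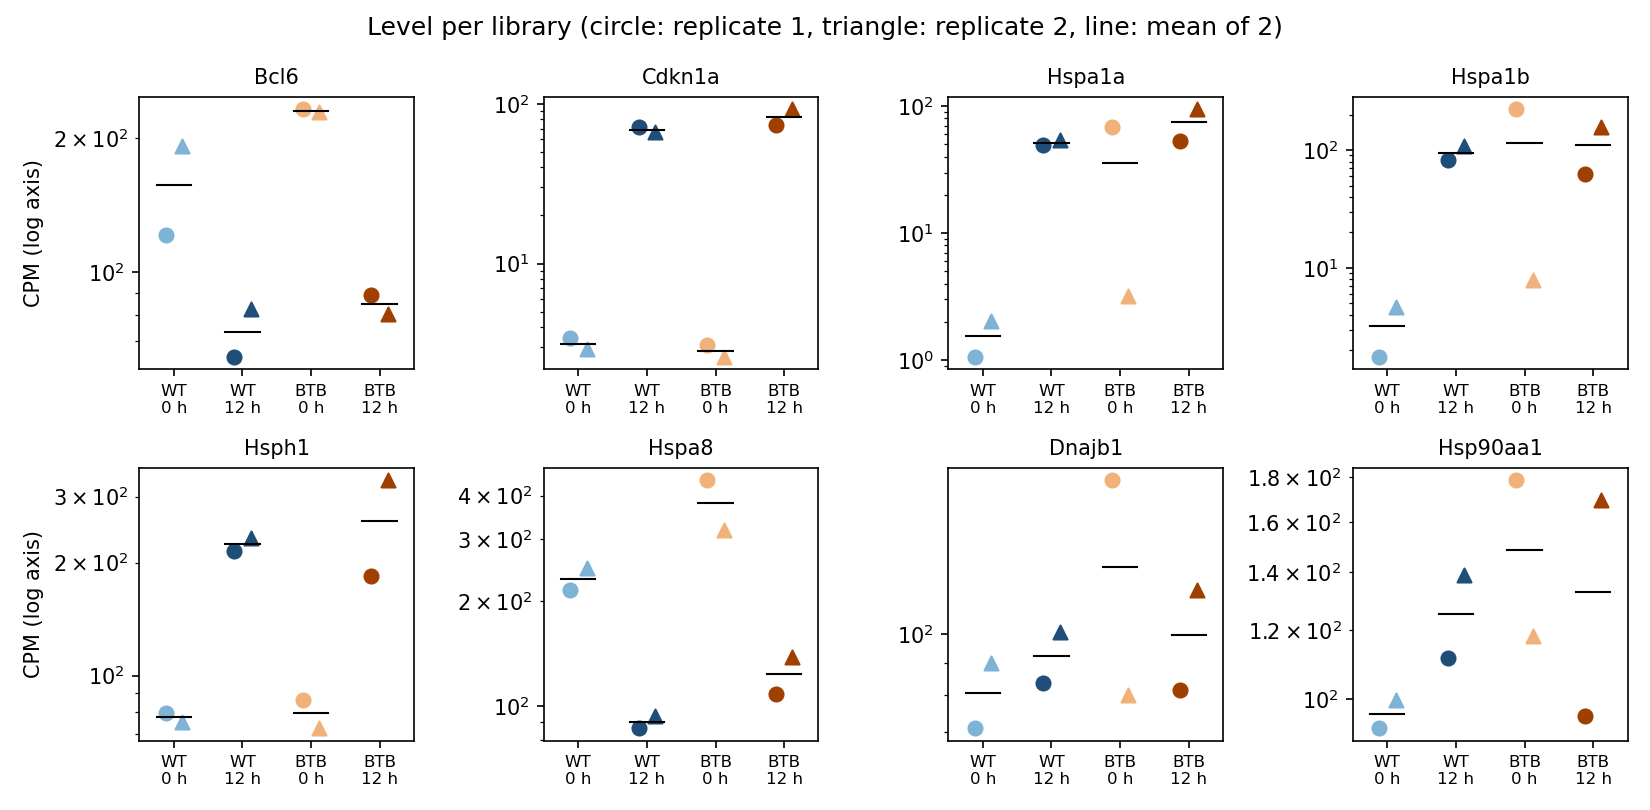
Levels of 8 genes named in advance in each library (CPM, log axis), with circles for replicate 1, triangles for replicate 2 and lines for the mean of 2. In BTB T0 replicate 1, Hspa1b stands at 224 CPM, against 7.93 in replicate 2.

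Camera called 12 lists in BTB, 6 up and 6 down, and none of these calls held with an estimated correlation. Genes of the amino acid and integrated stress response rose in 23 of 24 and fell in 0 (median 3.40; camera adjusted p = 2.71e-17, and adjusted p = 0.210 with an estimated correlation). Oxidative stress genes rose in 13 and fell in 1 of 19 (camera adjusted p = 8.37e-05, and adjusted p = 0.583 with an estimated correlation). Targets of p53 rose in 13 and fell in 4 of 21 (camera adjusted p = 0.00355, and adjusted p = 0.210 with an estimated correlation). Activation and NF-kB genes rose in 21 and fell in 6 of 30 (camera adjusted p = 8.86e-05, and adjusted p = 0.119 with an estimated correlation). Bcl6 targets rose in 18 and fell in 8 of 30 (camera adjusted p = 0.0302, and adjusted p = 0.210 with an estimated correlation). Among them the immune checkpoint ligand Cd274 rose by 2.27 ± 0.07. Plasma cell genes rose in 10 and fell in 1 of 17 (camera adjusted p = 0.0340, and adjusted p = 0.647 with an estimated correlation), with Ell2 at 1.81 ± 0.05 and Irf4 at 0.99 ± 0.09. B cell identity genes fell in 24 and rose in 2 of 30 (camera adjusted p = 1.64e-12, and adjusted p = 0.0640 with an estimated correlation). Interferon-stimulated genes fell in 24 and rose in 0 of 30 (camera adjusted p = 1.36e-08, and adjusted p = 0.381 with an estimated correlation). Immediate early genes fell in 17 and rose in 4 of 25 (camera adjusted p = 2.93e-05, and adjusted p = 0.595 with an estimated correlation). Cell cycle genes fell in 23 and rose in 2 of 30 (camera adjusted p = 4.68e-05, and adjusted p = 0.647 with an estimated correlation). Marginal zone genes fell in 12 and rose in 2 of 16 (camera adjusted p = 6.75e-05, and adjusted p = 0.210 with an estimated correlation). Myeloid markers fell in 10 and rose in 0 of 19 (camera adjusted p = 0.00573, and adjusted p = 0.595 with an estimated correlation). Adjusted over the list alone, the counts differed for activation and NF-kB (22 rose), Bcl6 targets (20 rose), B cell identity (25 fell), immediate early (18 fell) and myeloid (9 fell) genes, and were the same for the other 7.

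Camera did not call the remaining lists in BTB, and the adjusted p-values that follow are from camera. Fry called Bcl6 corepressors (fry adjusted p = 6.35e-04), apoptosis genes (0.00194) and mitochondrially encoded transcripts (0.0171) up, and dendritic cell genes (0.00331) down. Members that rose and fell numbered 9 and 4 of 26 heat shock genes (adjusted p = 0.418) and 8 and 7 of 22 endoplasmic reticulum stress genes (0.625). For apoptosis genes these were 7 and 6 of 21 (0.483) and for Bcl6 corepressors 9 and 5 of 20 (0.344). They numbered 9 and 8 of 27 DNA repair genes (0.997) and 8 and 13 of 24 trafficking genes (0.316). Germinal center genes rose in 1 and fell in 4 of 14 (0.444), and cholesterol synthesis genes in 6 and 7 of 24 (0.908). For glycolysis and hypoxia they were 10 and 14 of 29 (0.625), for ribosome biogenesis 4 and 9 of 25 (0.625), for the proteasome 7 and 13 of 30 (0.625) and for mitochondrially encoded transcripts 4 and 2 of 8 (0.344). Markers of T and NK cells rose in 12 and fell in 10 of 25 (0.969), of dendritic cells in 3 and 9 of 16 (0.0801), and of red cells and platelets in 4 and 1 of 17 (0.358). Adjusted over the list alone, the counts were the same except for Bcl6 corepressors (9 and 6), trafficking (8 and 14), glycolysis and hypoxia (11 and 14) and ribosome biogenesis (4 and 8). Median, mean and test differed in sign for DNA repair (median -0.14, mean -0.04, test up), cholesterol synthesis (-0.10, 0.06, up), glycolysis and hypoxia (-0.35, 0.07, down), ribosome biogenesis (0.02, -0.07, down) and T and NK cells (0.32, -0.01, up).

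Ackr3, which encodes a scavenging chemokine receptor, and the kinase gene Stk38l responded differently in the 2 genotypes. Xist and Y genes (below) point to female WT and male BTB libraries. Sex and genotype therefore cannot be told apart in this contrast, for genes or for lists. Ackr3 (ENSMUSG00000044337, chromosome 1, 90203980 to 90216751) went from 25.1 ± 3.88 to 1.58 ± 0.468 CPM in WT and from 22.0 ± 1.72 to 13.8 ± 0.322 CPM in BTB, a difference between responses of 3.31 ± 0.26. Stk38l (ENSMUSG00000001630, chromosome 6, 146724995 to 146778812) went from 20.2 ± 0.523 to 62.4 ± 6.67 CPM in WT and from 12.1 ± 0.768 to 12.1 ± 0.405 CPM in BTB, a difference of -1.63 ± 0.13. Both had an adjusted p of 0.0325 (edgeR's quasi-likelihood test of the interaction with Benjamini-Hochberg adjustment), and they were the 2 genes called of 15692, with 1415 at an unadjusted p under 0.05. With the replicate number within genotype as a block 8 genes were called. DESeq2 called 67 genes, edgeR without a low-count filter 17, and with a covariate for red cell genes (chosen after the data were seen) 4, each including Ackr3 and Stk38l, while limma-voom called 0 (1369 at an unadjusted p under 0.05). Leaving out any 1 of the 8 libraries gave 0 calls with edgeR (737 to 2847 at an unadjusted p under 0.05), with Ackr3 between 3.04 and 3.65 and Stk38l between -1.74 and -1.52.

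Across all 15692 genes the log2 fold changes of WT and BTB had a Pearson r of 0.910 and a Spearman rho of 0.914, with genes not being independent replicates, and r was 0.961 over the 7938 genes with a mean log2 CPM of at least 4. Both genotypes called 4138 genes upward, where independent sets would share 1461, and 4208 downward, where they would share 1573. Genes called upward in WT and downward in BTB numbered 5, and the reverse 8. None of the 13 genes named in advance passed the test of the difference, and Hspa1a (-4.03 ± 1.60), Hspa1b (-4.97 ± 1.80), Tox (2.31 ± 0.89), Prdm1 (0.69 ± 0.21), Cdkn1a (0.42 ± 0.21) and Bcl6 (-0.35 ± 0.29) had adjusted p between 0.533 and 0.715. With 1 library left out, the difference ran from -4.97 to -0.54 for Hspa1a and from -5.93 to -1.11 for Hspa1b. Camera called 14 lists, 12 of them with higher responses in BTB, and none held with an estimated correlation, where the lowest adjusted p was 0.285. A higher response can be a smaller fall or a lower start. Medians of BTB against WT at T0 and T12 were -0.64 and 0.0644 for cell cycle genes and -1.12 and -0.35 for germinal center genes. Both lists had medians below 0 from T0 to T12 in each genotype. Against WT, red cells and platelets were at -0.85 and 0.0343, oxidative stress genes at -0.32 and 0.13, and activation and NF-kB genes at 0.0502 and 0.17. Fry called 2 lists, both higher in BTB, p53 targets (median 0.18, fry adjusted p = 0.0389; camera adjusted p = 0.00712, and adjusted p = 0.430 with an estimated correlation) and activation and NF-kB genes (0.16, fry adjusted p = 0.0481; camera adjusted p = 1.12e-04, and adjusted p = 0.285 with an estimated correlation). Cell cycle genes had a median difference of 0.69 (camera adjusted p = 6.04e-11, and adjusted p = 0.461 with an estimated correlation). Markers of red cells and platelets moved the same way, all 17 lying between 0.53 and 1.30 with a median of 0.86 (camera adjusted p = 0.0243, and adjusted p = 0.822 with an estimated correlation), as did those of T and NK cells with a median of 0.40 (camera adjusted p = 3.04e-04, and adjusted p = 0.461 with an estimated correlation). For germinal center genes it was 0.80 (camera adjusted p = 1.72e-05, and adjusted p = 0.461 with an estimated correlation) and for oxidative stress genes 0.47 (camera adjusted p = 3.04e-08, and adjusted p = 0.461 with an estimated correlation). No member of these 7 lists was called over all genes, and adjusted over the list alone 1 p53 target, 2 T and NK cell and 5 oxidative stress genes were, among them Txnrd1 (0.53 ± 0.08). The other 5 lists higher in BTB were the amino acid and integrated stress response (0.28; camera adjusted p = 2.71e-05, and adjusted p = 0.461 with an estimated correlation), endoplasmic reticulum stress (0.20; camera adjusted p = 1.39e-04, and adjusted p = 0.613 with an estimated correlation), plasma cells (0.31; camera adjusted p = 1.18e-05, and adjusted p = 0.461 with an estimated correlation), the proteasome (0.15; camera adjusted p = 1.57e-05, and adjusted p = 0.610 with an estimated correlation) and mitochondrially encoded transcripts (0.20; camera adjusted p = 0.00383, and adjusted p = 0.461 with an estimated correlation). The 2 lower in BTB were interferon-stimulated (-0.18; camera adjusted p = 0.00518, and adjusted p = 0.735 with an estimated correlation) and trafficking genes (-0.0982; camera adjusted p = 0.0243, and adjusted p = 0.752 with an estimated correlation). None of their members was called over all genes, and adjusted over the list alone 2 plasma cell and 2 mitochondrially encoded genes were.

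**Figure D4:**
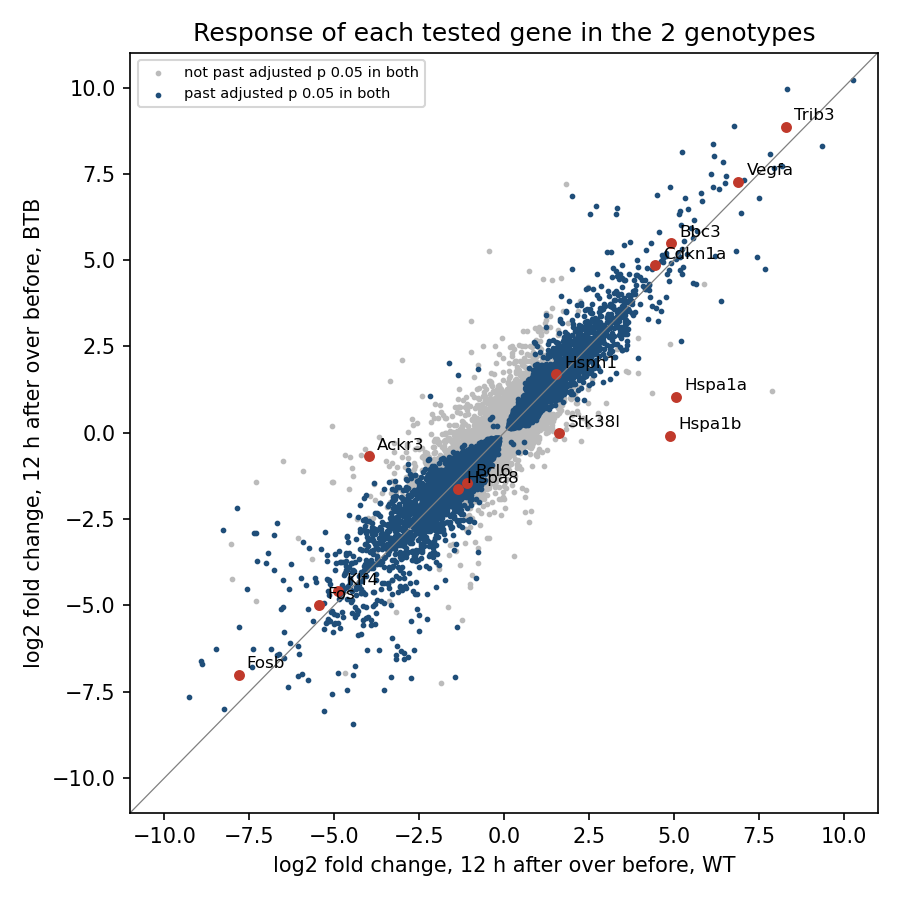
Log2 fold change from T0 to T12 of each tested gene in WT (horizontal) and in BTB (vertical), with genes named in the text in red and the grey line at equal responses. Pearson r across the 15692 genes is 0.910.

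Before heat shock, BTB cells differed from WT in genes of the X and Y chromosomes and in a set of autosomal genes. Xist (ENSMUSG00000086503), the RNA of X inactivation in females, was at 1258 ± 44.3 CPM in WT and 2.91 ± 3.02 in BTB (-8.78 ± 1.03, adjusted p = 0.0128). Ddx3y, Eif2s3y, Kdm5d and Uty of the Y chromosome, chosen after their values were seen, lay at or below 0.388 CPM in the 4 WT libraries and at or above 30.4 CPM in the 4 BTB libraries. The antiviral deaminase gene Apobec3 (ENSMUSG00000009585, chromosome 15, 79891659 to 79915906) was at 663 ± 5.45 CPM in WT and 50.3 ± 0.258 in BTB (-3.72 ± 0.05, adjusted p = 1.82e-07). Lower in BTB were also the ribosomal protein genes Rpl34 (-3.62 ± 0.11) and Rpl3 (-2.80 ± 0.08), for which processed copies elsewhere in the genome make the assignment of reads uncertain, the Wnt secretion gene Wls (-2.31 ± 0.23) and the phosphatase gene Ptpn14 (-1.83 ± 0.16). Higher in BTB were D2hgdh (1.38 ± 0.09), Ipcef1 (1.27 ± 0.13), Klhl9 (1.12 ± 0.16), Lef1 (1.06 ± 0.08), Ide (1.02 ± 0.05) and Sspn (0.87 ± 0.13). In total 136 genes differed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 48 higher and 88 lower, with 1938 at an unadjusted p under 0.05. A count without X and Y genes, chosen after the data were seen, gave 121.

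Bcl6 was at 231 ± 2.96 CPM in BTB and 157 ± 50.2 in WT at T0 and was not called (0.56 ± 0.20). Not called either were Hspa1a (4.56 ± 1.27), Hspa1b (5.18 ± 1.44), Hspa8 (0.72 ± 0.17), Tox (-2.57 ± 0.68) and Prdm1 (-0.59 ± 0.15). Without BTB T0 replicate 2, Hspa1a was at 5.49 and Hspa1b at 6.13. Over the left-out libraries their log2 fold changes went as low as 1.07 and 1.31. The high BTB means came from BTB T0 replicate 1 (68.7 and 224 CPM), as replicate 2 had 3.19 and 7.93 CPM. DESeq2 called Hspa1a (0.0187), Hspa1b (0.0128), Hspa8 (4.93e-05) and Tox (0.0124) at this time, against edgeR's 0.184, 0.182, 0.125 and 0.158. With the replicate number as a block, edgeR called Tox (0.0311) and Prdm1 (0.0424, against 0.152). Over 19 alternatives the adjusted p ran from 0.00722 to 0.792 for Hspa1a, 0.00695 to 0.883 for Hspa1b, 4.93e-05 to 0.554 for Hspa8, 0.0113 to 0.681 for Tox and 0.0424 to 0.699 for Prdm1. Germinal center genes had a median of -1.12 in BTB relative to WT. Of these, 0 of 14 were called over all genes, and 12 lower and 1 higher when adjusted over the list alone (camera adjusted p = 6.15e-09, and adjusted p = 0.553 with an estimated correlation). Among them S1pr2 was at -3.80 ± 0.65 and Nuggc at -3.67 ± 0.72. Cell cycle genes had a median of -0.64, with 0 of 30 called and 12 lower adjusted over the list alone (camera adjusted p = 3.40e-11, and adjusted p = 0.553 with an estimated correlation). Red cell and platelet genes had a median of -0.85, and all 17 were negative, between -1.24 and -0.0770. That list was not called (camera adjusted p = 0.144, and adjusted p = 0.770 with an estimated correlation) but was with the replicate number as a block (4.26e-05), and both it and the cell cycle list had medians above 0 for replicate 2 against replicate 1. Interferon-stimulated genes had a median of 0.33, with 0 of 30 called and 9 higher adjusted over the list alone (camera adjusted p = 7.00e-11, and adjusted p = 0.553 with an estimated correlation). Myeloid markers had a median of -1.35, with 1 of 19 called, Cd68, and 9 lower adjusted over the list alone (camera adjusted p = 3.98e-10, and adjusted p = 0.553 with an estimated correlation).

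Camera also called oxidative stress genes lower in BTB at T0 (camera adjusted p = 4.13e-05, and adjusted p = 0.553 with an estimated correlation), with 1 of 19 called, Txnrd1 (-0.36 ± 0.05), and 4 adjusted over the list alone. Lower too were the amino acid and integrated stress response with 0 of 24 called (camera adjusted p = 0.00551, and adjusted p = 0.770 with an estimated correlation). Plasma cell genes were lower with 1 of 17 called, Ell2 (camera adjusted p = 0.00460, and adjusted p = 0.621 with an estimated correlation), and T and NK cell markers with 1 of 25, Cd28 (camera adjusted p = 0.00460, and adjusted p = 0.621 with an estimated correlation). Adjusted over the list alone these had 0, 6 and 2 lower members, with 1 plasma cell gene higher, and none of the 8 calls at T0 held with an estimated correlation, or with fry, which called 0 lists. The count of 136 was 428 with DESeq2, 228 with limma-voom, 556 without a low-count filter, 497 with the replicate number as a block and 463 with the covariate for red cell genes. Leaving out 1 library lowered the count in most fits and raised it without either BTB T12 library. Each of these fits leaves 1 group with a single library.

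At T12, Xist, Apobec3, Rpl34, Rpl3 and Ptpn14 were again lower in BTB than in WT. Xist was at 1142 ± 141 CPM in WT and 5.95 ± 6.47 in BTB (-7.61 ± 0.97). Apobec3 was at 461 ± 4.74 and 27.3 ± 0.120 (-4.08 ± 0.05, adjusted p = 1.13e-07) and Ptpn14 at 72.6 ± 13.8 and 7.25 ± 0.0987 (-3.32 ± 0.18). Rpl34 (-4.30 ± 0.12), Rpl3 (-2.63 ± 0.09) and Slc40a1 (-2.60 ± 0.34) were lower as well. D2hgdh (1.53 ± 0.10), Rmnd1 (1.21 ± 0.11), the chemokine gene Ccl22 (1.21 ± 0.16), Slc45a4 (1.18 ± 0.06), Ide (0.91 ± 0.05) and Sspn (0.88 ± 0.13) were higher. In all, 154 genes differed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 63 higher and 91 lower, with 2402 at an unadjusted p under 0.05. Without X and Y genes, 145 differed. Genes called at both times numbered 27 higher and 47 lower in BTB, and 0 were called in opposite directions. How many the 2 times would share without a difference between genotypes is not known, as they may come from the same animals. No gene named in advance was called at T12 in this comparison: Bcl6 was at 0.20 ± 0.21, Hspa1a at 0.52 ± 1.01, Cdkn1a at 0.27 ± 0.13 and Prdm1 at 0.10 ± 0.15.

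Activation and NF-kB genes had a median of 0.17 in BTB at T12, with 1 of 30 called, Ccl22, and 6 higher adjusted over the list alone (camera adjusted p = 9.42e-06, and adjusted p = 0.154 with an estimated correlation), and theirs was the 1 list called with fry (adjusted p = 0.0227). Mitochondrially encoded transcripts had a median of 0.24 with 1 of 8 called, mt-Nd1, and 4 adjusted over the list alone (camera adjusted p = 2.55e-04, and adjusted p = 0.721 with an estimated correlation). Myeloid markers had a median of -0.65, with Csf1r called at -2.32 ± 0.36 and 2 higher and 5 lower adjusted over the list alone (camera adjusted p = 4.89e-04, and adjusted p = 0.721 with an estimated correlation). Interferon-stimulated genes had a median of 0.32, while their only called member, Gbp3, was lower (-0.59 ± 0.08; camera adjusted p = 0.0171, and adjusted p = 0.721 with an estimated correlation). Proteasome genes had a median of 0.12 with 0 of 30 called (camera adjusted p = 0.00118, and adjusted p = 0.721 with an estimated correlation). The count of 154 was 405 with DESeq2, 414 without a low-count filter, 62 in a fit of the 4 T12 libraries, 274 with the replicate number as a block and 444 with the covariate for red cell genes. Left-out libraries gave 50 without WT T12 replicate 1, 56 without WT T12 replicate 2, 91 without BTB T0 replicate 1, 92 without BTB T0 replicate 2, 367 without BTB T12 replicate 1 and 74 without BTB T12 replicate 2.

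**Figure D5:**
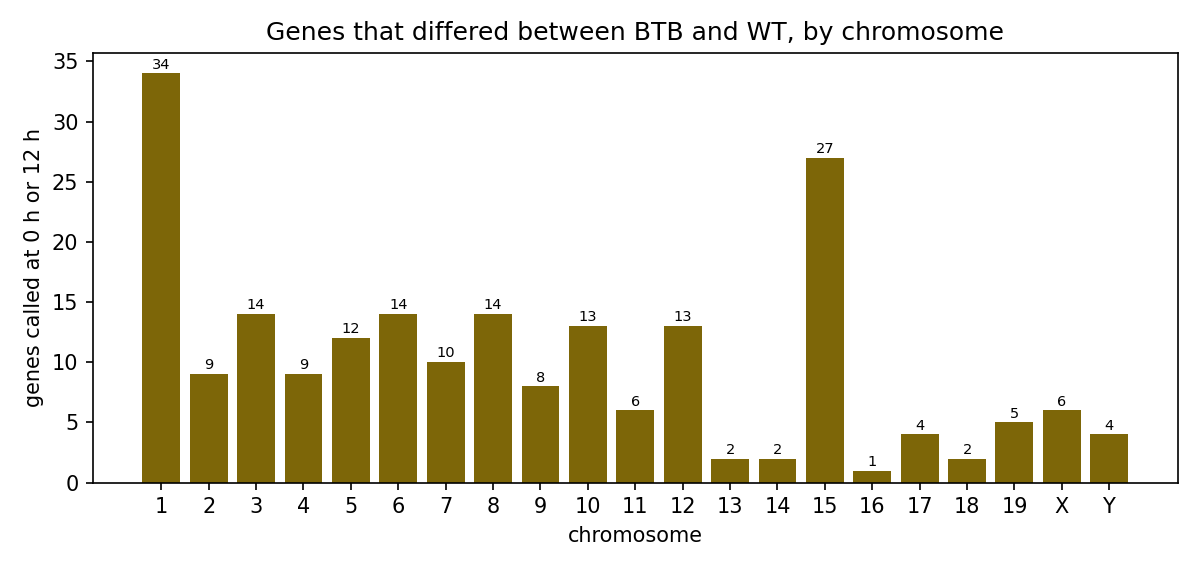
Number of genes that differed between BTB and WT at T0 or T12, by chromosome. Chromosome 1 holds 34 and chromosome 15 holds 27, and 4 of the 7 tested Y genes differed.

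The authors deposited a table of genes for the change between T0 and T12 in each genotype, with 5730 genes for WT and 5573 for BTB, of which 4716 were in both. Of the 5674 WT and 5532 BTB genes of these tables that were tested here, 100% had the same sign, and 5545 and 5384 were called here too. Another 4356 genes in WT and 4232 in BTB were called here and not listed there. The file names point to tables kept to genes with a human identifier and above a CPM limit. That limit is low, as the tables reach down to a mean log2 CPM of -2.97 and -2.99. How much of the surplus comes from these limits and how much from calling was not tested. In the authors' tables Hspa1a stood at a log2 fold change of 5.11 in WT, Cdkn1a at 4.47 in WT and 4.85 in BTB, and Bcl6 at -1.05 in WT and -1.45 in BTB. These tables come from the same libraries and are not an independent test.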

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

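The tests on sex, strain segments and Bcl6 targets were chosen after the result was seen, and the test of a segment around Bcl6 before.

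Ackr3 (3.31) and Stk38l (-1.63) stand out because their log2 responses to T12 differed between BTB and WT in a test of the difference itself. No technical explanation was tested for them, and sex cannot be told apart from genotype in this test. Stk38l lies 0.0629 Mb from Arntl2 and Ackr3 0.754 Mb from Rab17, the nearest genes called between genotypes.

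Among genes that differ between BTB and WT at T0 or T12, Xist and the 4 Y genes, 5 of 5, parted all WT from all BTB libraries in the directions that female WT and male BTB animals would give, so a difference in sex may account for the X and Y genes. For the 199 called autosomal genes, sex cannot be told apart from genotype, because each genotype has libraries of 1 sex. A segment around Bcl6 carried with the mutation would hold none of this set, since 0 of the 199 lie within 10 Mb of Bcl6. Whether such a segment is carried cannot be told from this, as 0 is within the spread of random draws (median 2). Segments of another strain stay open: 111 called genes had another within 2 Mb, above the median of 84 and below the highest of 120 among 10000 draws, of which 12 gave as many. Loss of repression of Bcl6 targets stays open too, with a median of 0.0740 and a mean of -0.0792 at T0 over members that went both ways: 1 of 30 was called, higher, and adjusted over the list alone 2 were higher and 5 lower (camera adjusted p = 0.440, and adjusted p = 0.770 with an estimated correlation).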

How the results depend on the processing

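Alternatives with a covariate for red cell genes or without X and Y genes were chosen after the result was seen, and the others before. Counts for WT and BTB between T0 and T12 stayed within 1.5 times under every alternative except a log2 fold change of at least 1, which by construction left 4232 and 4122, and ran from 8125 to 10308 and from 7728 to 9692 with 1 library left out. The agreement across genotypes was 0.961 over genes with a mean log2 CPM of at least 4. Genes with a different response numbered 17 without a low-count filter, 67 with DESeq2, 0 with limma-voom (1369 at an unadjusted p under 0.05), 8 with the replicate number as a block, 4 with the red cell covariate, and 0 to 0 with 1 library left out in edgeR (737 to 2847 at an unadjusted p under 0.05). Genes between genotypes at T0 numbered 556 without a filter, 428 with DESeq2, 228 with limma-voom, 497 with the number as a block (Tox and Prdm1 among them), 463 with the red cell covariate and 35 to 166 with 1 library left out. At T12 they numbered 84 with a log2 fold change of at least 1, 414 without a filter, 405 with DESeq2, 274 with the number as a block, 62 in a fit of 4 libraries, 444 with the red cell covariate and 50 to 367 with 1 library left out. The lower counts with a fold limit follow from its construction. Leaving out a library lowered some counts and raised others. For this and the other alternatives, the cause was not tested.

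Over all alternatives, values of the genes named in advance, Ackr3 and Stk38l kept their direction and status, called or not, in 1147 cases. They lost the call in 27, gained it in 16 and took the opposite sign in 27. For lists, tested only with an estimated correlation, fry and the block, these numbers were 312, 73, 12 and 8. Both 1147 and 312 include values that were not called in the first place and stayed uncalled, so they do not count calls that held. Fry called 17 lists in WT, 16 in BTB, 2 in the interaction, 0 at T0 and 1 at T12. Opposite signs were as follows, with the range over the left-out libraries, and the cause was not tested. In WT, Tox ran from -0.43 (without WT T0 replicate 2) to 1.31, with -0.33 without WT T12 replicate 1. In BTB, Hspa1b was at 1.17 with limma-voom and 0.99 with the block, and ran from -1.02 to 3.79 (without BTB T0 replicate 1), with 0.43 without BTB T12 replicate 1. Hsp90aa1 ran from -0.64 to 0.19 (without BTB T12 replicate 1), with 0.17 without BTB T0 replicate 1, and Dnajb1 from -0.82 to 0.32 (without BTB T0 replicate 1). In the interaction, Hsph1 ran from -0.32 (without BTB T12 replicate 2) to 0.53, Dnajb1 from -1.03 to 0.11 (without BTB T0 replicate 1) and Hsf1 from -0.0403 (without WT T0 replicate 2) to 0.19. At T0, Hsph1 ran from -0.0918 (without BTB T0 replicate 1) to 0.16, with -0.00601 without WT T0 replicate 2. Dnajb1 ran from -0.00316 (without BTB T0 replicate 1) to 1.14, and Hsf1 from -0.0590 (without WT T0 replicate 1) to 0.17, with -0.0162 without BTB T0 replicate 1. At T12 the opposite signs came without BTB T12 replicate 2 for Hspa1b (-0.61 to 0.72), Hsph1 (-0.28 to 0.57), Hsp90aa1 (-0.39 to 0.43), Dnajb1 (-0.18 to 0.35), Atr (-0.17 to 0.0326), Prdm1 (-0.0480 to 0.24) and Tox (0.0644 within -0.70 to 0.25), and without WT T12 replicate 1 for Tox (0.25), Hsp90aa1 (-0.0703) and Dnajb1 (-0.0230). Hspa1b without BTB T0 replicate 1 was the only one of these that was called. Lists whose direction turned, none of them called, had adjusted p of 0.950 (red cells and platelets in WT), 0.898 (glycolysis and hypoxia in BTB), 0.985 (cholesterol synthesis at T0) and 0.836 (red cells and platelets at T12) with the block, and of 0.302 (glycolysis and hypoxia in BTB), 0.661 (T and NK cells in BTB) and 0.983 (apoptosis and DNA repair in the interaction) with fry. No list called by camera changed the sign of its median under the other scalings. The spread between libraries limits these values, and for genes with few counts, such as Tox, depth may limit them too.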

Other observations

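The tests of gene families, of red cell RNA and of both explanations for Hspa1a and Hspa1b were chosen after the result was seen, and the test of a lower share of B cells before.

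Genes of antigen presentation, protein synthesis, lysosomes, respiration and chromatin were grouped by symbol in 10 families, over which p-values were adjusted, and no family changed the sign of its median under 3 other scalings. All 11 measured class II histocompatibility genes, which include Cd74 and Ciita, fell in both genotypes, with medians of -2.30 in WT and -2.48 in BTB (camera adjusted p = 4.12e-11 and 1.70e-11; with an estimated correlation adjusted p = 0.0404 and 0.0383). Several of them are also in the list of B cell identity, and markers of dendritic and myeloid cells, which express class II genes as well, also had medians below 0, of -1.82 and -1.09 in WT and -1.90 and -0.89 in BTB. Of 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 15 rose and 4 fell in each genotype, with medians of 1.55 and 1.57 (adjusted p = 0.235 and 0.180 with an estimated correlation). Aars, Sars and Wars among them are also in the list of the amino acid and integrated stress response.

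Of 16 subunits of the V-type proton pump, which acidifies lysosomes, 13 rose and 2 fell in WT and 11 rose and 2 fell in BTB (adjusted p = 0.0631 and 0.0566 with an estimated correlation). Cytosolic ribosomal protein genes fell in 57 and rose in 2 of 79 in WT, and fell in 47 and rose in 4 in BTB (adjusted p = 0.537 and 0.706 with an estimated correlation). Autophagy genes rose in 15 of 27 in WT and 17 in BTB, with 1 lower in each (adjusted p = 0.510 and 0.494 with an estimated correlation). Nuclear NADH dehydrogenase subunits fell in 22 and rose in 1 of 36 in WT, where camera called them (adjusted p = 0.578 with an estimated correlation), and fell in 14 and rose in 4 in BTB, where it did not; the responses differed by a median of 0.19 (camera adjusted p = 1.19e-05, and 0.705 with an estimated correlation). The other 4 families, mitochondrial ribosomal proteins, class I histocompatibility genes, histones and zinc finger genes, were not called in either genotype. Between genotypes camera called histones (medians 0.39 and 0.60) and cytosolic ribosomal proteins (0.0855 and 0.19) higher in BTB at T0 and T12, zinc finger genes at T0 (0.0891), and mitochondrial ribosomal proteins (0.12) and NADH dehydrogenase subunits (0.17) at T12. Responses were higher in BTB for both ribosomal families (0.0958 and 0.11) and lower for zinc finger genes (-0.15), and with an estimated correlation no family was called between genotypes, the lowest adjusted p being 0.451.

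Hspa1a and Hspa1b were high before heat shock in BTB replicate 1, at 68.7 and 224 CPM. RNA like that of the BTB T12 libraries mixed into that library is argued against. For it, 42 other genes raised 8-fold or more needed a median share of 0.0937%, against 92.0% for Hspa1a and 211.7% for Hspa1b. The shares were computed from BTB T12 levels, so they cannot decide on RNA of cells taken sooner after heat. A heat shock response in the cells of that library is a candidate explanation: the other 24 members of the heat shock list had a median log2 ratio of 0.0681 ± 0.12 (SE) to replicate 2, 15 of them above 0, at percentile 99.51 of 10000 random lists, with Dnajb1 at 176 against 80.0 CPM. That margin is narrow, as the median is smaller than its SE. No biological explanation from the design was tested.

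Genes of red cells and platelets were higher in replicate 2 of each group. Of 17 measured, 88.2% were higher in all 4 groups, against 8.60% of all genes, and Hbb-bs stood at 642 and 2350 CPM in WT at T0, so red cell or erythroid RNA may be a source, which a sort for B220 would remove if it were complete. The test of a lower share of B cells looked only at markers of other white cells. The T and NK cell, myeloid and dendritic lists had medians of at most 0.0574 in log2, against 1.77 for the red cell and platelet list. A matching rise of those white cells is argued against. The test cannot tell whether red cells or their precursors lowered the share of B cells. Cell cycle genes were also higher in replicate 2, with a median of 0.34 and 13 of 30 higher in all 4 groups. No biological explanation from the design was tested.

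Genes called between genotypes lay close together in places, the largest being chromosome 15 from 79.3 to 86.1 Mb, with 14 called of 109 tested, Apobec3 and Rpl3 among them. The immunoglobulin heavy chain region of chromosome 12 held 13 called genes, and chromosome 15 from 73.2 to 75.0 Mb held 8 of 20. Without the 12 immunoglobulin genes, 100 of 187 called genes had another within 2 Mb, against a random median of 75, and 19 of 10000 draws gave as many.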
